A study of Mus musculus with 251 samples.

How the data were processed

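The series holds single-cell RNA sequencing of dendritic cell (DC) precursors from the bone marrow of male C57BL/6 mice at steady state. Per the labels' protocols, cells were enriched with magnetic beads, sorted by flow cytometry, captured on a microfluidic chip, lysed and amplified there, and made into Nextera XT libraries with dual indices. Each sample is 1 cell, and 251 cells fall into 3 sorted populations: 59 MDP (macrophage and DC progenitor), 96 CDP (common DC progenitor) and 96 PreDC cells. All were CD45 positive, lineage negative and MHC class II negative by their gates. MDP and CDP cells were CD11c negative, FLT3 positive and CD115 positive, with MDP cells CD117 positive and CDP cells CD117 intermediate. PreDC cells were CD11c positive, FLT3 positive, CD172a negative and B220 negative.

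The authors deposited read counts per gene for each cell, in files without a header that hold 29863 genes and 5 counter lines. The submitters' processing notes name STAR, HTSeq and the mouse build mm9, with no versions. The counter lines for reads outside genes, ambiguous reads, low-quality alignments, unaligned reads and multiple alignments were left out of library sizes. Reads assigned to genes were a median of 30.9% of all lines in MDP, 32.9% in CDP and 33.8% in PreDC cells, reads outside genes 23.7%, 19.8% and 25.0%, and ambiguous reads 2.09%, 2.17% and 2.13%. Reads with several alignments were a median of 43.6% of all lines in MDP, 43.9% in CDP and 39.6% in PreDC cells, so genes with near-identical copies or overlapping neighbours are undercounted here. A table of RPKM values was also deposited by the authors for 29779 of the genes. Its values matched counts divided by gene length and by the sum of all lines of a cell, multiple alignments included: the gene length this implies varied over cells by a median CV of 1.34e-13% over 1616 genes, against 11.5% when gene reads were the divisor. RPKM served only as an alternative. The library type was not stated as stranded, so overlapping antisense genes cannot be told apart.

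A cell was kept with at least 1000 genes detected and at least 10% of the median gene reads of its population. For shares of cells, every kept cell was thinned once without replacement to 390000 reads, the 10th percentile of depth, and shallower cells were left out of thinned values. A gene counted as detected in a cell at 3 or more reads. Shares carry exact Clopper-Pearson 95% intervals over cells. Levels are mean CPM (a cell's counts scaled to the same total of gene reads in every cell) over all kept cells, with the SD over cells, and ratios are log2((mean CPM + 1)/(mean CPM + 1)). A gene counted as measured in a comparison when detected in at least 5% of the thinned cells of either population. The intervals cover counting error only: libraries had no molecular identifiers, and no animal, pool or chip is named.

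Because no label names an animal, a pool or a capture chip, each population is 1 sample. Cells are not replicates, so no test, p-value, standard error or count of differing genes is given, and a population cannot be told apart from the chip or day of its capture. Lists of genes were fixed before the data were examined, for stem and early progenitor, primary granule, late neutrophil, monocyte and macrophage, plasmacytoid DC (pDC), shared conventional DC (cDC), cDC1, cDC2, MHC class II, B lineage, T and NK, erythroid and megakaryocyte, mast cell and basophil, S phase, G2/M phase, immediate early and interferon-stimulated genes, DC transcription factors and myeloid growth factor receptors, with sort gate and sex genes as label checks. Gate genes were left out of the other lists. List members were matched by symbol, a written alias or a synonym from the RefSeq gene table of GRCm38, another build, used only for names. Ly6g, Hba-a1 and Hbb-b2 had no match. The median log2 ratio of each list's measured members was set beside 10000 random lists of the same size matched on mean expression in 20 bins. A list is said to stand apart when its median lies outside the central 95% of these. This describes these cells and is not a test.

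The genes named are all gate, sex and DC transcription factor genes, up to 4 measured members of each list with the largest difference in share, and the 10 genes with the largest higher and the 10 with the largest lower share in each comparison, among those with a log2 ratio of at least 1 in size and the same sign in mean log2(CPM + 1), leaving out gate, ribosomal protein, predicted and pseudogene names. Genes correlated with Siglech, Ly6c2 or Irf8 are those of the fixed lists with the largest positive and negative correlations. How many of them are named was chosen after the values were seen. Heat shock genes that were higher in PreDC than in CDP cells are named as well.

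Levels of lists were correlated across the thinned cells of 1 population as Spearman's rho of mean log2(CPM + 1), beside 1000 random list pairs. For correlations with the G2/M list, that list was kept and only the other list was drawn at random. Each cell was also compared by Pearson correlation over the 1000 most variable genes with the mean of each population, itself left out. Leiden clustering used 1000 variable genes, 10 principal components, 15 neighbours and resolution 1. No doublet caller was run on so few cells. The kept cell with the most genes had 6359 genes (MDP), 6076 (CDP) or 4207 (PreDC), beside medians of 4984.5, 4227 and 3330.5.

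The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, scanpy 1.11.5, leidenalg 0.10.2, python-igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and scran 1.30.0. They were tested on simulated data with 200 changed genes among 29863. For CDP against MDP the median recovered log2 ratio was 0.98 for genes set to 1, -1.11 for -1, 1.96 for 2 and -1.86 for -2. For PreDC against CDP it was 0.95, -0.99, 2.05 and -2.08. Of the simulated lists of unchanged genes, 3.33% and 3.67% stood apart. These lists were drawn at random from genes simulated independently, with the same detection share in both groups, so a low rate was built in. It does not cover lists whose members vary together or populations that differ in the number of genes detected. In these simulations, where few genes differed, 66.7% and 60.9% of cells were nearest their own group, against 58% and 42.5% with shuffled groups.

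Alternatives fixed beforehand were stricter and looser cell filters, scran size factors, the difference of mean log2(CPM + 1), summed counts, a pseudocount of 10 CPM, no filter on low genes, thinned cells, RPKM, detection at 1 or 10 reads, other thinning, other numbers of list genes or variable genes, and other cluster resolutions. After the data were seen, 1 more was added: a gene then counted as detected in a cell only at 3 or more reads and at least 1% of the mean level of the cell's own population, as an allowance for reads passing between wells.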

Results

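Single DC precursors of mouse bone marrow were sequenced to describe how the precursor populations relate to each other and how cells within each population differ. Of 251 cells, 58 of 59 MDP, 95 of 96 CDP and 96 of 96 PreDC cells were kept. Reads assigned to genes per kept cell ranged from 185831 to 1567595 in MDP (median 1041650), from 154380 to 945425 in CDP (median 637100) and from 87996 to 993294 in PreDC cells (median 564671). After thinning to 390000 reads, 57 MDP, 85 CDP and 82 PreDC cells remained, with 1, 10 and 14 too shallow. PreDC cells held fewer genes than CDP cells, and CDP cells fewer than MDP cells: the median was 4382 genes in MDP (SD 504 over cells), 3968 in CDP (SD 613) and 3082 in PreDC cells (SD 335) at equal depth. Without thinning the medians were 4984.5, 4227 and 3330.5 genes. With 1 sample per population there are no replicates, so the SDs and intervals given here describe cells and counting, not animals. Where a gene was detected in 0 thinned cells, 3 cells would be a share of 5.26% in MDP, 3.53% in CDP and 3.66% in PreDC cells, and the exact 95% interval reaches up to 6.27%, 4.25% and 4.40%.

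Transcripts of the proteins used for sorting were read as a check of the labels. Kit, the gene of CD117, was detected in 84.2% (72.1 to 92.5%) of MDP and 27.1% (18 to 37.8%) of CDP cells, matching the order of the gates. Itgax, the gene of CD11c, was detected in 0% of MDP, 21.2% of CDP and 54.9% of PreDC cells. Csf1r, the gene of CD115, was found in 71.9% of MDP, 77.6% of CDP and 28% of PreDC cells, while the PreDC gate did not use it. Flt3 was present in 80.7%, 71.8% and 73.2%, and Ptprc, the gene of CD45, in 89.5%, 88.2% and 93.9%. Sirpa, the gene of CD172a, was detected in 25.6% (16.6 to 36.4%) of PreDC cells despite the CD172a negative gate. H2-Ab1, an MHC class II chain, was detected in 5.26% of MDP, 5.88% of CDP and 79.3% (68.9 to 87.4%) of PreDC cells, all sorted as MHC class II negative, and in 42.7% of PreDC cells when a level of at least 1% of the PreDC mean was also required. The Y-linked genes Eif2s3y (63.2%, 56.5% and 39%), Uty (40.4%, 36.5% and 23.2%) and Kdm5d (10.5%, 9.41% and 6.10%) were detected in all populations, and Xist in 1 of 85 CDP cells and no other. Ddx3y, also Y-linked, had no read in any kept cell.

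CDP cells had lower levels of progenitor and granule genes than MDP cells and higher levels of DC genes. Mpo, the myeloperoxidase of neutrophil granules, averaged 9178 ± 6500.4 CPM (SD over cells) in MDP and 2025 ± 3282 CPM in CDP cells. Siglech, a surface receptor of pDCs, was not detected in MDP cells and was found in 30.6% (21 to 41.5%) of CDP cells. Irf8, a transcription factor needed for DC development, averaged 627 ± 740.0 CPM in MDP and 2348 ± 1461 CPM in CDP cells and was detected in nearly all cells of both, 98.2% and 100%. Immediate early genes, which cells switch on within minutes of a stimulus, were lower in CDP cells, and G2/M genes were higher.

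All 10 measured members of the primary granule list were lower in CDP than in MDP cells, with a median log2 ratio of -1.60 (0th percentile of random lists; central 95% from -0.53 to 0.54). Ctsg, the protease cathepsin G, was detected in 87.7% (76.3 to 94.9%) of MDP and 52.9% (41.8 to 63.9%) of CDP cells, Elane, neutrophil elastase, in 43.9% and 18.8%, Nkg7 in 57.9% and 22.4%, and Cebpa, a transcription factor of granulocyte and monocyte progenitors, in 35.1% and 11.8%. Of 16 measured stem and early progenitor genes, 12 were lower and the median was -1.11 (percentile 0). Cd34 was detected in 94.7% (85.4 to 98.9%) of MDP and 68.2% (57.2 to 77.9%) of CDP cells, Lmo2, a transcriptional cofactor of early haematopoiesis, in 96.5% and 60%, Ifitm1 in 68.4% and 30.6%, and Angpt1, the ligand angiopoietin 1, in 38.6% and 3.53%.

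Of 10 measured pDC genes, 9 were higher in CDP cells, with a median of 2.54 (percentile 100). Besides Siglech, Runx2 was detected in 57.9% (44.1 to 70.9%) of MDP and 94.1% (86.8 to 98.1%) of CDP cells, Cd300c in 0% and 28.2%, and Bst2 in 43.9% and 71.8%. Of 9 measured shared cDC genes, 7 were higher (median 1.42, percentile 100), among them Id2, an inhibitor of E proteins required for cDC1s, in 5.26% (1.10 to 14.6%) and 30.6% (21 to 41.5%), and Kmo, an enzyme of tryptophan breakdown, in 14% and 63.5%. Dpp4 was detected in 38.6% and 58.8% and Ccr7 in 0% and 15.3%. The cDC1 list had a median of 1.11 with 5 of 8 genes higher (percentile 99.5). Clec9a, a receptor of cDC1s for dead cells, was detected in 0% of MDP and 23.5% (15 to 34%) of CDP cells, whereas Cd24a was found in fewer CDP cells, 89.5% and 78.8%. With RPKM values this list no longer stood apart, at 0.33. Only 5 cDC2 genes were measured, 3 of them higher (median 1.60, percentile 99.7), Clec10a in 1.75% and 24.7%; 5 of the 9 alternative settings, among them thinned cells at 1.11, brought this list inside the random range, and its median difference in share was -1.07 percentage points.

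The monocyte and macrophage list was higher in CDP cells in 11 of 13 genes (median 0.95, percentile 99.97). Ly6c2 was detected in 40.4% (27.6 to 54.2%) of MDP and 78.8% (68.6 to 86.9%) of CDP cells, Klf4, a transcription factor of monocytes, in 26.3% and 50.6%, S100a4 in 7.02% and 30.6%, and Cx3cr1 in 43.9% and 64.7%. Of 6 measured MHC class II genes 4 were higher (median 1.44, percentile 99.5): these were accessory genes of antigen presentation, H2-DMb1 in 15.8% and 55.3%, H2-DMb2 in 1.75% and 16.5% and H2-DMa in 87.7% and 94.1%, and H2-Oa in 7.02% and 17.6%. Ly6c2 has near-identical relatives, so its level is uncertain.

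All 21 G2/M genes were higher in CDP than in MDP cells, with a median of 0.96 (percentile 100). Aurkb, a mitotic kinase, was detected in 45.6% (32.4 to 59.3%) of MDP and 69.4% (58.5 to 79%) of CDP cells, Cenpf in 29.8% and 55.3%, and Nusap1 in 36.8% and 60%. The S phase list did not stand apart (19 genes, median -0.11, mean log2 ratio 0.14, percentile 41.4), with Mcm2 lower at 77.2% and 60% and Rrm2, a subunit of ribonucleotide reductase, higher at 75.4% and 88.2%. Of 13 immediate early genes 11 were lower in CDP cells (median -1.98, percentile 0). Egr1 was detected in 78.9% (66.1 to 88.6%) of MDP and 12.9% (6.64 to 22%) of CDP cells, Fos in 93% (83 to 98.1%) and 37.6% (27.4 to 48.8%), Fosb in 63.2% and 17.6%, and Dusp1, a phosphatase that ends MAP kinase signalling, in 70.2% and 24.7%. Heat shock genes, of which this list holds 2, were also lower in CDP cells, in 10 of 10 with a median of -0.98. They were not among the lists above and were not set beside random lists. The interferon-stimulated (8 genes, median -0.50, percentile 12.7), DC transcription factor (17 genes, 0.21, percentile 86.1), growth factor receptor (12 genes, 0.48, percentile 95.1) and B lineage lists (4 genes, 0.02, percentile 58.5) did not stand apart. The B lineage list had a median difference in mean log2(CPM + 1) of -0.26 and in share of -3.38 percentage points. Among receptors, Csf3r, the receptor of the granulocyte growth factor G-CSF, was lower, at 47.4% (34 to 61%) and 15.3% (8.40 to 24.7%), and Cxcr4, the receptor that holds cells in the marrow, higher, at 50.9% (37.3 to 64.4%) and 87.1% (78 to 93.4%). Among markers of other lineages, 2 late neutrophil genes (Cxcr2 and Mmp8), 1 T and NK gene (Klrb1c), 1 mast cell gene (Mcpt8) and no erythroid or megakaryocyte gene were measured. Each was detected in at most 12.3% of MDP cells. Without thinning, the shares in MDP and CDP cells were 96.6% and 65.3% for Cd34, 0% and 30.5% for Siglech, 1.72% and 24.2% for Clec9a and 84.5% and 13.7% for Egr1, at median depths that differed as given above. As differences of mean log2(CPM + 1), list medians moved by over 1.5 times to 1.25 for pDC, 0.52 for cDC1, 0.68 for MHC class II and 1.48 for G2/M genes, and with RPKM to -0.70 for stem and early progenitor genes.

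Across all genes, the shares higher in CDP than in MDP cells by the most were those of Mpeg1 (40.4% and 91.8%), a pore-forming protein of phagocytes, Ahnak (28.1% and 88.2%), the protease Ctsh (31.6% and 88.2%), Rnase6 (7.02% and 60%), Tcf19 (17.5% and 68.2%), Itgb7 (8.77% and 55.3%), Tmem119 (5.26% and 50.6%), Scpep1, Cfp and Kmo. Those lower by the most were Egr1, Pde4b (80.7% and 21.2%), Cd69 (75.4% and 18.8%), an early activation antigen, Fos, Myc (82.5% and 29.4%), Srm, a spermidine synthase (77.2% and 24.7%), Smyd5, Nsun2, Dusp2 and the translation factor subunit Eif3b (89.5% and 42.4%).

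**Figure D1:**
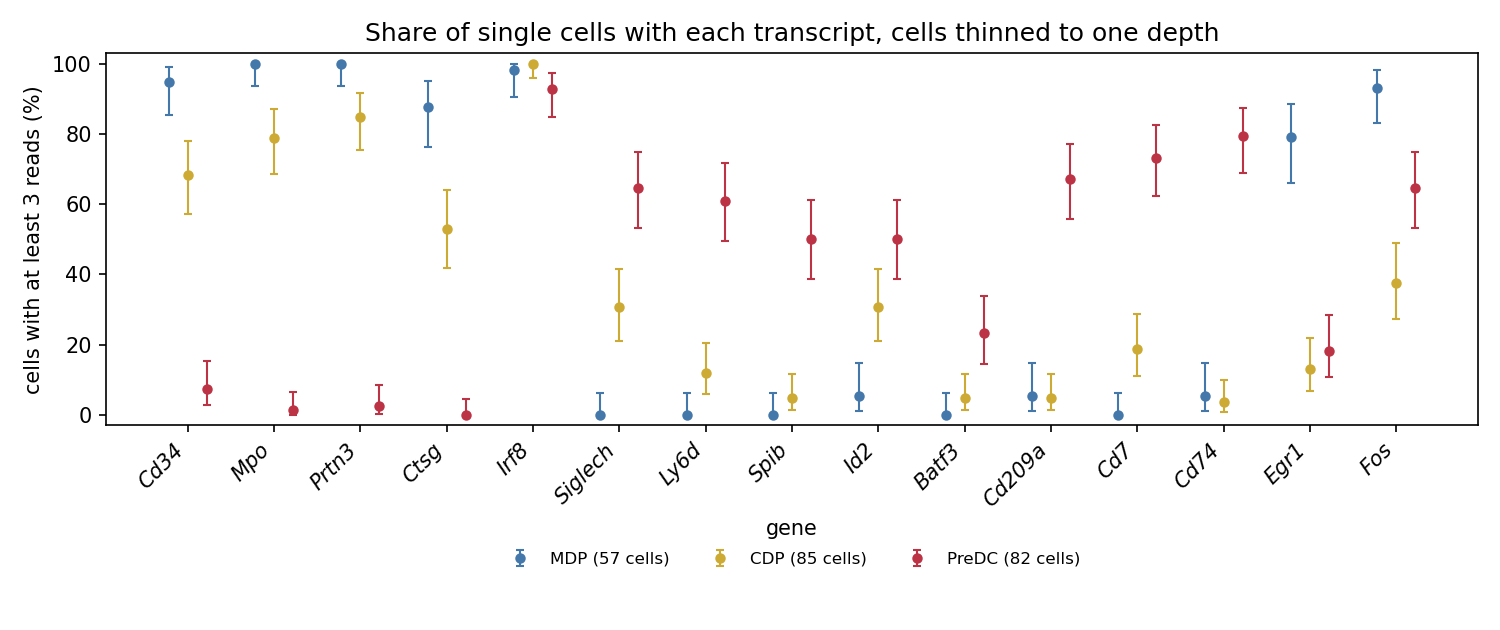
Share of thinned cells with at least 3 reads (y axis, percent) for 15 genes (x axis) in MDP, CDP and PreDC cells, with exact 95% Clopper-Pearson intervals that cover counting error only. Mpo was detected in 100%, 78.8% and 1.22% of cells and Siglech in 0%, 30.6% and 64.6%.

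Mpo, Prtn3, Ctsg and Elane were each detected in at most 2.44% of PreDC cells, while Srgn, also on the primary granule list, was found in 61%. PreDC cells had higher levels of pDC, cDC and MHC class II genes than CDP cells. Mpo was detected in 78.8% (68.6 to 86.9%) of CDP cells and in 1 of 82 PreDC cells, 1.22% (0.0309 to 6.61%). Siglech was detected in 64.6% (53.3 to 74.9%) of PreDC cells at 1384 ± 2002 CPM, against 233 CPM in CDP cells, and Cd74, the MHC class II invariant chain, in 79.3% (68.9 to 87.4%) at 3475 ± 5845 CPM (median 97.4 CPM over thinned cells) against 1.89 CPM. Cycling genes were detected in fewer PreDC than CDP cells. Irf8 averaged a similar level in both, 2348 and 2354 CPM, but was detected in 76 of 82 PreDC cells against 100% of CDP cells. At a level of at least 1% of the population mean, its share was 84.1% (74.4 to 91.3%) in PreDC and 100% (95.8 to 100%) in CDP cells.

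Of 10 primary granule genes, 9 were lower in PreDC cells, with a median of -3.55 (percentile 0) or -5.86 with genes without a PreDC read set at 3 reads over the population. The size of this median depended on the scale, and it was -1.81 with a pseudocount of 10 CPM, -1.87 as a difference of mean log2(CPM + 1) and -1.91 with RPKM. Prtn3, proteinase 3, was detected in 84.7% (75.3 to 91.6%) of CDP and 2.44% (0.297 to 8.53%) of PreDC cells, and Ctsg in 52.9% and 0%. At a level of at least 1% of the population mean, the share with Mpo was 65.9% in CDP cells. Of 13 stem and early progenitor genes, 11 were lower (median -0.99, percentile 0.75), with Cd34 in 68.2% and 7.32% (2.73 to 15.2%), Myb in 90.6% and 40.2%, Cd27 in 54.1% and 12.2% and Cdk6 in 44.7% and 4.88%. Cells with 3 or more primary granule genes were 100% of MDP, 91.8% of CDP and 8.54% of PreDC cells (3.50 to 16.8%), and cells with 3 or more stem and early progenitor genes were 100%, 94.1% and 23.2% (14.6 to 33.8%).

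Of 14 measured pDC genes, 13 were higher in PreDC cells (median 2.64, percentile 100). Ly6d was detected in 11.8% (5.79 to 20.6%) of CDP and 61% (49.6 to 71.6%) of PreDC cells, Spib, a transcription factor of pDCs, in 4.71% (1.30 to 11.6%) and 50% (38.7 to 61.3%), and Cox6a2 in 23.5% and 41.5%. Shared cDC genes were higher in 10 of 13 (median 1.77, percentile 100), with Id2 in 50% (38.7 to 61.3%), Slamf7 in 2.35% and 32.9% and Btla in 10.6% and 29.3%, while Runx3 was lower, 71.8% and 46.3%. Of 10 cDC1 genes, 9 were higher (median 1.23, percentile 99.96), among them Batf3, a transcription factor cDC1s require, in 4.71% (1.30 to 11.6%) and 23.2% (14.6 to 33.8%), Ifi205 in 7.06% and 26.8% and the RNA sensor Tlr3 in 0% and 13.4%. Clec9a, found in 20.7% of PreDC cells, had overlapping intervals in both. Cd24a, also on this list, was found in fewer PreDC cells, 53.7% (42.3 to 64.7%) against 78.8% (68.6 to 86.9%) of CDP cells. The 6 measured cDC2 genes had a median of 0.81 (percentile 98.4), led by Cd209a in 4.71% (1.30 to 11.6%) and 67.1% (55.8 to 77.1%), while Tmem176b was lower, 70.6% and 40.2%; with scran size factors, no filter on low genes or thinned cells, this list no longer stood apart.

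All 9 MHC class II genes were higher in PreDC cells (median 1.88, percentile 100). H2-Aa was detected in 1.18% (0.0298 to 6.38%) of CDP and 80.5% (70.3 to 88.4%) of PreDC cells, H2-Eb1 in 2.35% and 48.8%, and Ciita, the master activator of these genes, in 0% and 23.2% (14.6 to 33.8%). Requiring at least 1% of the PreDC mean lowered the PreDC shares to 51.2% for Cd74, 40.2% for H2-Aa, 35.4% for H2-Eb1, 45.1% for Cd209a, 48.8% for Ly6d and 53.7% for Siglech, each still above the CDP share. The monocyte and macrophage list had a median of 1.02 with 9 of 12 genes higher (percentile 99.97), Cybb, a subunit of the phagocyte oxidase, in 18.8% and 57.3%. F13a1, coagulation factor XIII, was lower, 83.5% (73.9 to 90.7%) and 14.6% (7.80 to 24.2%), and so was Ly6c2, 78.8% and 58.5%.

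S phase genes were lower in 18 of 19 (median -0.73, percentile 0.01) and G2/M genes in 19 of 21 (median -0.50, percentile 0.32). The median difference in share was -29.8 percentage points for S phase and -26.7 for G2/M genes. PreDC cells held fewer genes at equal depth (median 3082 against 3968 in CDP cells). No median difference in share over all measured genes was taken. By difference of mean log2(CPM + 1), the medians were -2.53 for S phase and -1.89 for G2/M genes, against -0.53 for all measured genes. Both lists lay outside random lists matched on expression on that scale too. This argues against a general loss of detection as the whole of these drops, while a part of them may still come from it. Rrm1 was detected in 95.3% (88.4 to 98.7%) of CDP and 58.5% (47.1 to 69.3%) of PreDC cells, Fen1 in 81.2% and 30.5%, Bub1, a mitotic checkpoint kinase, in 55.3% and 19.5% and Cdk1 in 69.4% and 32.9%. Immediate early genes were higher in PreDC than in CDP cells in 11 of 13 (median 1.31, percentile 100), with Fos in 64.6% (53.3 to 74.9%), Zfp36 in 42.4% and 64.6% and Btg2 in 50.6% and 78%. That median was the value of Hspa1a, a heat shock gene detected in only 5.88% of CDP and 2.44% of PreDC cells. The median difference in share of the list was 11.9 percentage points. All 4 measured interferon-stimulated genes were higher (median 2.02, percentile 99.9), Ifi27l2a in 38.8% and 52.4%. The 4 measured B lineage genes had a median of 1.03 (percentile 98.5), with Il7r in 5.88% and 24.4% and Blnk in 4.71% and 24.4%, while Cd79b was lower, 38.8% and 11%; scran size factors or no filter on low genes ended this. No late neutrophil, T and NK, erythroid or mast cell gene was measured.

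DC transcription factors had a median of 0.53 (20 genes, 14 higher, percentile 99.7), but a median difference in share of -5.16 percentage points. Bcl11a was detected in 52.6% of MDP, 74.1% of CDP and 87.8% of PreDC cells, Tcf4 in 94.7%, 96.5% and 90.2% at 339, 420.2 and 1188 CPM, and Klf4 in 26.3%, 50.6% and 61%. Runx1 had the opposite order, 94.7%, 83.5% and 56.1%. Irf4 and Zbtb46 were detected only in PreDC cells, each in 8.54% (3.50 to 16.8%). Cebpa and Nfil3 were found in 7.32% and 4.88% of PreDC cells, and Gfi1 was not detected. The PU.1 gene, listed as Sfpi1, was found in 33.3%, 37.6% and 19.5%. Shares of Mef2c (98.2%, 100% and 85.4%), Ikzf1 (93%, 85.9% and 84.1%) and Zeb2 (93%, 77.6% and 63.4%) had mean levels in another order, so none is read from them. Id3, Bcl6 and Relb were each found in at most 13.4% of the cells of any population. The growth factor receptor list stood at 0.53 (12 genes, 7 higher, percentile 97.2), inside the random range, while its median difference was -0.41 in mean log2(CPM + 1) and -9.71 percentage points in share. Without thinning, the shares in CDP and PreDC cells were 84.2% and 1.04% for Mpo, 65.3% and 7.29% for Cd34, 30.5% and 72.9% for Siglech and 3.16% and 88.5% for Cd74. As differences of mean log2(CPM + 1), with the median of all genes at -0.53, list medians moved by over 1.5 times to 1.29 for pDC, 0.83 for shared cDC, 0.59 for cDC1, 0.36 for cDC2, 0.60 for monocyte and macrophage, 0.70 for immediate early, 0.56 for interferon-stimulated and 0.0039 for DC transcription factor genes. Those of stem and early progenitor, S phase and G2/M genes moved to -1.58, -2.53 and -1.89.

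Across all genes, Cd7 (18.8% (11.2 to 28.8%) of CDP and 73.2% (62.2 to 82.4%) of PreDC cells), Rnd3 (20% and 63.4%), Fgr, a Src-family kinase (5.88% and 46.3%), and Plbd1 (3.53% and 42.7%) joined Cd74, H2-Aa, Cd209a, Ly6d, H2-Eb1 and Spib among the shares higher by the most. Besides Mpo, Prtn3, F13a1, Cd34 and Ctsg, the shares lower by the most were those of Igfbp4, which binds insulin-like growth factors (88.2% and 18.3%), Gpr97 (78.8% and 17.1%), Slpi (77.6% and 17.1%), Cst7 (81.2% and 26.8%) and Ptpn7 (77.6% and 24.4%). Between MDP and PreDC cells, Mpo was detected in 100% and 1.22%, Cd34 in 94.7% and 7.32%, and Siglech, Ly6d, Cd7 and Spib were found in no MDP cell. Mean levels correlated across genes with a Spearman rho of 0.84 for CDP and MDP, 0.80 for PreDC and CDP and 0.74 for PreDC and MDP cells. Genes are not independent replicates.

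**Figure D2:**
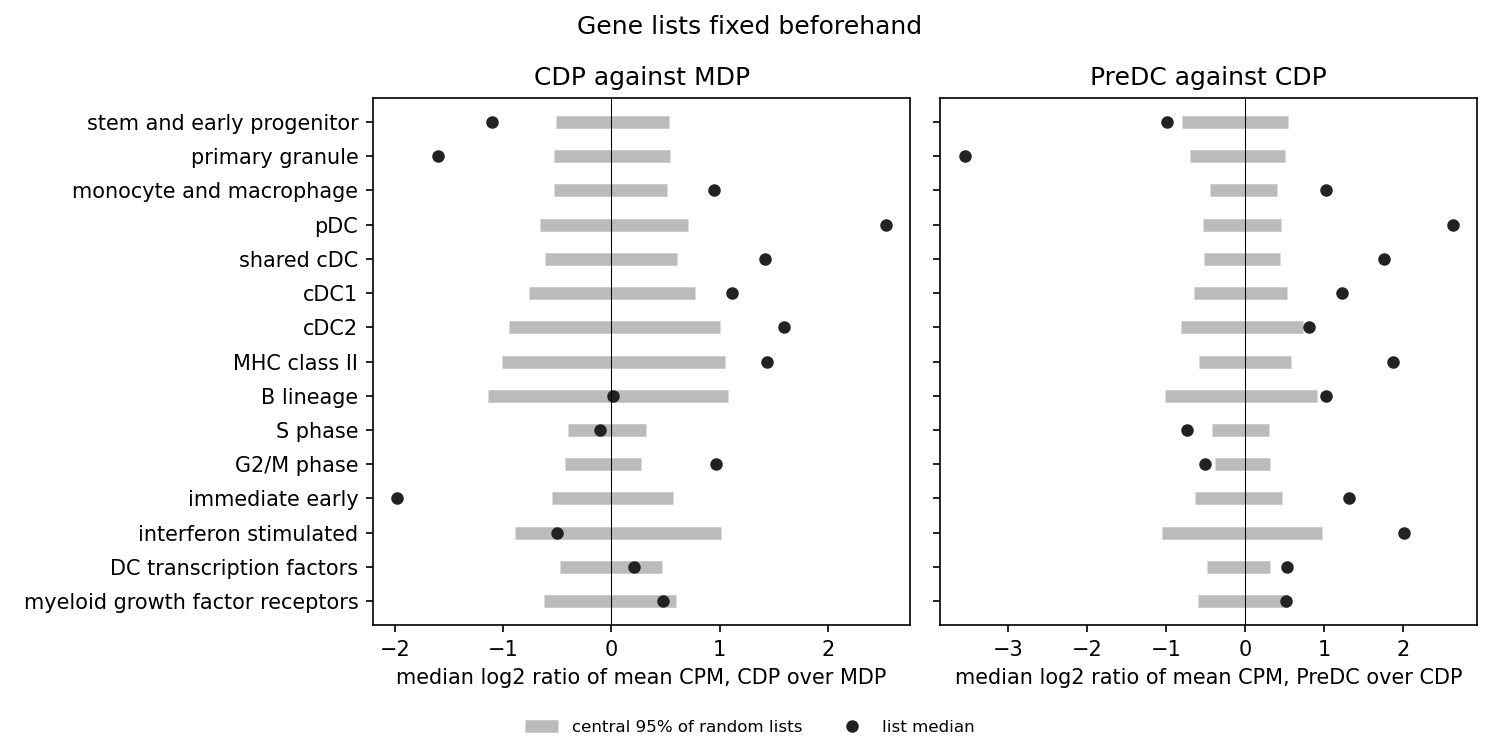
Median log2 ratio of mean CPM (x axis) for each gene list (y axis) in CDP against MDP and PreDC against CDP cells, as points, with bars for the central 95% of 10000 random lists matched on expression. The primary granule list lies at -1.60 and -3.55, and the pDC list at 2.54 and 2.64.

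Within populations, single cells differed in the levels of these lists. Across 82 PreDC cells, the pDC list ran against the shared cDC list (Spearman rho -0.56, central 95% of random list pairs from -0.08 to 0.37), the cDC1 list (-0.46) and the monocyte list (-0.38), and not against the cDC2 list (-0.00). The shared cDC list went with the cDC1 list (0.50), and the cDC2 list with the monocyte list (0.49), while the cDC1 and cDC2 lists ran against each other (-0.32). Cells higher in shared cDC genes were lower in stem and early progenitor genes (-0.47). Across 85 CDP cells, the pDC list ran against the primary granule list (-0.57; random pairs from -0.06 to 0.37) and the monocyte list (-0.25), and its correlation with the shared cDC list was 0.10, inside the random range. Cells with 3 or more pDC genes made up 50.9% of MDP, 84.7% of CDP and 84.1% of PreDC cells, and those with 3 or more monocyte genes 93%, 97.6% and 91.5%. The shares were 91.2%, 100% and 98.8% for shared cDC genes, 87.7%, 89.4% and 75.6% for cDC1 genes and 19.3%, 20% and 28% for cDC2 genes, and 0, 2 and 5 cells held 3 or more B lineage genes. Across 57 MDP cells, the monocyte list ran against the stem and early progenitor list (-0.54), and the pDC list against the primary granule list (-0.34).

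**Figure D3:**
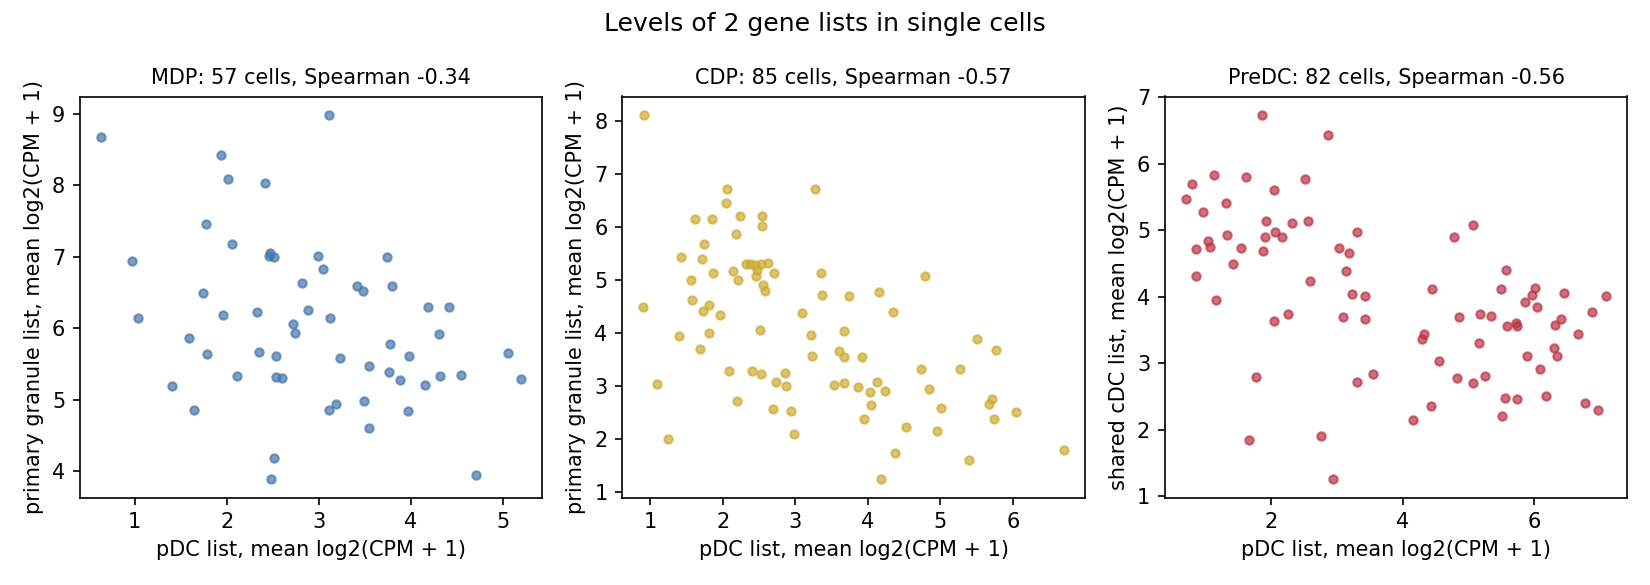
Each point is 1 thinned cell, with the mean log2(CPM + 1) of the pDC list on the x axis and that of the primary granule list (MDP and CDP cells) or the shared cDC list (PreDC cells) on the y axis. The Spearman rho was -0.34, -0.57 and -0.56.

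Siglech and Ly6c2, surface markers by which PreDC cells can be divided, were detected together in 38 of 82 PreDC cells (46.3%, 35.3 to 57.7%), Siglech alone in 15, Ly6c2 alone in 10 and neither in 19. If independent, 31.02 cells (37.8%) would carry both. Over 3874 genes, Siglech correlated across PreDC cells with the pDC genes Ly6d (rho 0.71), Tcf4 (0.70), Cox6a2 (0.65) and Atp1b1 (0.59), and ran against Ccr2 (-0.62), Batf3 (-0.61), Lyz2 (-0.61) and Slamf7 (-0.60). Ly6c2 correlated with Bst2 (0.50), Runx2 (0.48) and Siglech (0.44) and ran against the MHC class II genes H2-Eb1 (-0.51), H2-Aa (-0.50), Cd74 (-0.50) and Ciita (-0.48). Irf8 correlated with Siglech (0.48) and ran against Cd209a (-0.49). No cells were sorted into groups by these genes for any other comparison. The share with both was 52.1% without thinning, where independence gives 44.8%, and 36.6% at 10 or more reads, where it gives 26.8%. At 1 or more reads it was 73.2%, where independence gives 72.6%, so the excess depended on the number of reads required. At that threshold Siglech was found in 90.2% and Ly6c2 in 80.5% of PreDC cells, which leaves less room for an excess.

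Most cells resembled their own population, gate genes left out. By correlation over 1000 variable genes, 56 of 57 MDP (98.2%), 77 of 85 CDP (90.6%, 82.3 to 95.8%) and 78 of 82 PreDC cells (95.1%, 88 to 98.7%) were nearest the mean of their own population. Of the other CDP cells, 6 were nearest the MDP mean and 2 the PreDC mean. Of the other PreDC cells, 2 were nearest the MDP mean and 2 the CDP mean, and the remaining MDP cell was nearest the CDP mean. Clustering of all 224 cells gave 9 clusters, left without names, in which 87.1% of cells belonged to the most frequent population of their cluster. Cluster 2 held 9 CDP and 29 PreDC cells and cluster 8 held 7 and 8, clusters 5 and 6 held only PreDC cells (20 and 19), and clusters 1 and 9 held 53 of the 57 MDP cells. Cluster 1 also held 2 PreDC cells and 1 CDP cell, beside 40 MDP cells. CDP cells alone and PreDC cells alone gave 6 clusters each. Each population may differ from the others by its capture chip or day as well.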

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

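The tests by the shares of MDP and CDP cells with immediate early genes, of PreDC cells with MHC class II genes and of PreDC cells with Cd74, and by the part of the Cd74 level in the highest cells, were chosen only after the results were seen. Wells left out of every comparison were not empty. CDP cell 46 held 1267 reads assigned to genes and MDP cell 51 held 1336, far above the 3 reads that a count of 0 allows, 0.199% and 0.128% of the median of their populations. They held 938 and 964 genes. Both (2 of 2) had more genes than every kept cell of the same population thinned to the same reads (at most 885 and 945). A number within that range had been predicted for a single cell whose amplification failed. Many genes per read was already part of the pattern under test, so this count in part restates it. Both (2 of 2) correlated with the mean of their population (0.39 and 0.40) better than every thinned cell did (at most 0.37 in either population). This fits a mix of reads from other wells, which may add a few reads of very abundant transcripts to other cells, and no biological explanation was tested. The 2 measures are not independent, since a well with more genes at the same reads can also correlate better with a mean.

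PreDC cells were sorted as MHC class II negative, yet Cd74, H2-Aa and H2-Ab1 averaged 3475, 3620.4 and 2979.8 CPM, means carried by part of the cells, since the median of Cd74 over thinned cells was 97.4 CPM. With the allowance of 1% of the PreDC mean for each gene, 52.4% of PreDC cells (41.1 to 63.6%) held 3 or more MHC class II genes (79.3% without it), against 25.9% of CDP (17 to 36.5%) and 8.77% of MDP cells. The list holds accessory genes common in CDP cells, such as H2-DMa (94.1%) and H2-DMb1 (55.3%), so this count alone cannot decide. Cd74 was found in 51.2% of PreDC and 3.53% of CDP cells, and H2-Eb1 in 35.4% and 2.35%. H2-Aa was found in 40.2% of PreDC (29.6 to 51.7%) and 1.18% of CDP cells. At 1 or more reads, Cd74 was found in 93.9% and H2-Aa in 97.6% of PreDC cells. How many reads passed between wells was not measured. If they stayed below the 1% allowance, the shares at that allowance argue against a few mature cells as the source of the detection. As the source of the mean level they stay open: the 8 highest of 82 cells held 48.5% of the summed Cd74 level (37 to 62.1% over 2000 resamples, describing these cells only), an interval that holds the bound of 50% below which they were to be excluded. Cd74 lay above 1% of the PreDC mean in 51.2% of cells (39.9 to 62.4%), where a lower bound above 50% had been asked for. Reads passing between wells are therefore not excluded. For the cells below 1%, low expression and such reads cannot be told apart. Transcription of these genes before the protein reaches the surface is an open biological explanation and was not tested.

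Immediate early genes were lower in CDP than in MDP cells and higher again in PreDC cells: with all cells at 1 depth, 86% of MDP cells (74.2 to 93.7%) held 5 or more of the genes, against 23.5% of CDP (15 to 34%) and 43.9% of PreDC cells, which argues against read depth and against a small set of MDP cells. The ratio of mean CPM at 1 depth, the depth test set beforehand, was not used because thinning leaves it nearly fixed. Heat shock genes, 2 of which the list shares, were lower in CDP cells in 10 of 10, with a median of -0.98, just short of the -1 set beforehand for handling or capture of the MDP cells. No random lists were drawn for them, and the 2 shared genes were detected in only 10.5% and 14% of MDP cells. In PreDC against CDP cells, where immediate early genes were higher, 6 of 10 heat shock genes were lower and their median was -0.22. The 4 higher were Hspa1a (1.31), Hsph1 (0.91), Dnajb1 (0.79) and Hspa1b (0.05). Heat shock genes thus went both ways there, and their median cannot show whether some of them followed the immediate early genes. Handling of the MDP cells cannot be told apart from a difference between the progenitors, because each population is 1 sample with no chip or day named.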

How the results depend on the processing

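The allowance for reads between wells was chosen after seeing the data, and all other alternatives before. No paired analysis was possible because each population is 1 sample and no result comes from a test. Of 270 values of list medians under alternatives, 250 kept their direction and their side of the random range. Of 205 among these from lists that stood apart, 19 moved in size by over 1.5 times, as given with the results: 16 of 23 with the difference of mean log2(CPM + 1), 2 with RPKM and 1 with a pseudocount of 10 CPM. Another 3 changed sign, all of lists inside the random range before and after: for CDP against MDP the B lineage list with the difference of mean log2(CPM + 1) (-0.26) and the S phase list with summed counts (0.020), and for PreDC against CDP the growth factor receptors with the difference of mean log2(CPM + 1) (-0.41). For CDP against MDP, the cDC2 list no longer stood apart with the stricter cell filter (1.03), the difference of mean log2(CPM + 1) (0.093), no filter on low genes (0.57), thinned cells (1.11) and RPKM (0.54), and the cDC1 list with RPKM (0.33). The growth factor receptors stood apart only with the difference of mean log2(CPM + 1) (0.45), and interferon-stimulated genes only without a filter on low genes (-1.07). For PreDC against CDP, the cDC2 list no longer stood apart with scran size factors (0.86), no filter on low genes (0.43) and thinned cells (0.56), nor did the B lineage list with scran size factors (1.06) or no filter on low genes (0.034), while growth factor receptors did with the stricter cell filter (0.52), summed counts (0.51), a pseudocount of 10 CPM (0.47) and RPKM (0.53). The cDC2 list rests on 5 and 6 genes and the B lineage list on 4; the cause was not tested for any of these. Scran size factors moved the median of all genes in PreDC against CDP from -0.13 to -0.00, and the difference of mean log2(CPM + 1) moved it to -0.53 and that of CDP against MDP from -0.04 to -0.20. The share of PreDC cells with Siglech and Ly6c2 was 73.2% at 1 or more reads, where fewer reads suffice. Without thinning, the correlation of the pDC with the stem and early progenitor list across PreDC cells was 0.30, outside the random range drawn for thinned cells. The cells kept, and the share nearest their own population with other numbers of genes, without cycle genes or without thinning, did not move beyond their intervals. Clusters numbered 5 for all cells and 3 for CDP and for PreDC cells at resolution 0.5, and 8 or 9, 6 or 7 and 6 or 8 at resolution 1.5 or with more variable genes. Of 940 differences in share of named genes, 899 stayed within their intervals, 40 moved and 1 reversed: Junb in PreDC against CDP cells was at -0.70 percentage points at 10 or more reads. Of 126 shares of cells with list genes 67 moved: 16 when 2 list genes were required, 20 when 5 were, 17 at 1 or more reads, 12 at 10 or more reads and 2 without thinning. Of 63 list correlations, 57 kept their side of the random range without thinning. That range was the one drawn for thinned cells, and no random lists were drawn without thinning. Depth limits low genes most: a gene at fewer than 3 of 390000 reads in a cell was not counted.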

Other observations

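The test across CDP cells and the numbers of cell cycle genes required per cell were chosen only after results were seen. Cells with 10 or more G2/M genes made up 36.8% of MDP (24.4 to 50.7%), 67.1% of CDP (56 to 76.9%) and 30.5% of PreDC cells (20.8 to 41.6%). Cells with 10 or more S phase genes made up 91.2%, 88.2% and 46.3% (35.3 to 57.7%). PreDC cells held fewer genes of any kind at equal depth, which may lower such counts. Dntt, the terminal transferase of lymphoid progenitors, was detected in 21.1% (11.4 to 33.9%) of MDP, 9.41% (4.15 to 17.7%) of CDP and 12.2% (6.01 to 21.3%) of PreDC cells, with overlapping intervals, and Cd79b, a B cell receptor chain, in 43.9%, 38.8% and 11%. Il7r was detected in no MDP cell, in 5.88% of CDP and in 24.4% (15.6 to 35.1%) of PreDC cells, and Blnk in 1.75%, 4.71% and 24.4%. Tmem119 was detected in 50.6% (39.5 to 61.6%) of CDP cells and in 5.26% of MDP and 9.76% of PreDC cells.

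Whether cells leaning to one DC fate cycle more was tested across PreDC cells, with the prediction written beforehand. The prediction named random list pairs, but here the G2/M list was kept and only the other list was drawn at random. The G2/M list correlated with the pDC list at -0.021, below the median of these draws (0.25) but inside their central 95% (-0.04 to 0.52). The median had been set beforehand as the bound for exclusion, and the edge of the central 95% was put in its place after the result was seen, because a value inside that spread excludes nothing. The G2/M list correlated with the shared cDC list at -0.19, below the range of such draws (-0.01 to 0.52), against the idea that cells with higher shared cDC levels cycle more.

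Whether the opposition of pDC and shared cDC lists seen in PreDC cells starts earlier was asked across CDP cells. The correlation of these lists was 0.10 there (median of random pairs 0.18) and 0.23 across MDP cells, both inside the random range. The opposition was thus not detectable in these populations and is not excluded.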
